A study of Homo sapiens with 4 samples.

How the data were processed

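HepG2 cells were grown in 4 flasks, 2 kept for 72 hours at 2% oxygen and 2 at 20%, per the labels' protocols. Hypoxic and normoxic flasks were hybridised in 2 pairs, each in both dye orientations, on 4 arrays of 1 slide. The labels call the flasks of a condition biological replicates. Nothing states that the cells came from separate cultures before seeding. The p-values of single genes for hypoxia against normoxia therefore rest on the spread between these flasks only, pooled over all genes. The pairs are those hybridised together.

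The deposited scanner files hold, per the file headers, the intensity of each spot and of its local background in Cy3 and Cy5, as read by Agilent Feature Extraction 9.1.1.1. They also hold the software's processed intensity, which per the file headers was background-subtracted, detrended and dye-normalised with LOWESS (smoothing 0.25), and the log10 ratio of Cy5 over Cy3. A table of log2 ratios deposited by the authors covers 35445 of the 41000 probes. Against the scanner ratios its columns correlated between 0.99996 and 0.99999 in size, with a negative sign on the swapped arrays, so that it is already hypoxia over normoxia. Its column medians were -0.0011, -0.0903, 0.0812 and 0.0308, so it was not centred further. How its probes were chosen is not given in the sources used here.

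Background was corrected with normexp (offset 50) and arrays were normalized by loess with limma 3.58.1 in R 4.3.3. Control spots had no weight in loess and were left out afterwards, as were outlier spots. A change was made after the data were seen: on 2 of the 4 arrays normexp as first run failed, because 4 and 5 spots had local backgrounds far above their signal. The 25th percentile of log2 Cy5 on those arrays was 10.3 and 10.6, against 6.57 and 6.76 on the others. Spots that the scanner software marks for a non-uniform local background (70, 38, 36 and 18 per array) were therefore left out before normexp, after which the percentiles were 6.68 and 6.71. The choice followed those percentiles, and the results with the marked spots kept are given as an alternative.

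Probes were named through a table of RefSeq genes (assembly GRCh38.p14), of which only names were used. Of 41000 probes, 23434 matched by accession, 2317 by symbol and 1043 by an older symbol, 1652 kept the file's name and 12554 had no gene name. The build behind the array is not given in the sources used here, so no coordinates are given. A probe was kept if well above background on all 4 arrays in the hypoxic or in the normoxic channel. The probe with the highest mean intensity stood for a gene.

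Ratios were turned to hypoxia over normoxia and the 2 arrays of a pair averaged. The 2 pair means were tested in limma with an intercept and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 residual degree of freedom, eBayes estimated infinite prior degrees of freedom and a common SD of 0.349, so that each gene's own spread did not enter its p-value and the test acted as a threshold on the ratio. The dye orientation was tested over the 4 arrays with the pair as a term. A total of 45 gene lists were fixed before the data were examined, and the 44 with at least 5 measured genes were tested with camera (preset correlation 0.01, and an estimated correlation beside it). With the preset correlation camera compares the genes of a list with the other genes. Its p-values then do not measure the variation between flasks, and genes are not independent replicates. With an estimated correlation no list passed, with a smallest p of 0.072 and a smallest adjusted p of 0.69. In that form camera takes its p-values from the 1 residual degree of freedom of 2 pairs, so hardly any list could pass. The camera p of canonical hypoxia targets went from 6.84e-65 to 0.072. Failing this form therefore says little about a list.

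In simulated data on the same 12763 genes with 200 changed, the test recovered 10% of genes changed by 0.5 on the log2 scale, 78% of those changed by 1 and 100% of those changed by 2 or 4, and 3.36% of calls were unchanged genes. The simulation gave every gene the same spread, as the fit assumes, so it does not test that assumption. It also changed far fewer genes than the 3328 called in the data. The adjusted threshold depends on that share, so the recovered percentages do not carry over to the data.

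The genes named are the 12 largest rises and 12 largest falls that passed with 1 sign on all arrays and were well above background on all arrays in both conditions (placeholder names left out), up to 6 genes with only a bound, up to 4 passing members of each list and its brightest member where most did not pass, the 7 signature genes and 12 genes that check the labels. Some genes that the rule names are not reported here. Alternatives were the background correction, normalization, filter, probe rule, variance model, pairing, dye orientation, the authors' table and each pair left out. No probe was saturated, so leaving out saturated probes changed nothing. Figures were drawn with Python 3.11.15.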

Results

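Gene expression was measured in HepG2 cells, an established human liver tumour cell line of hepatoblast-like character, after 72 hours at 2% oxygen (hypoxia) or 20% oxygen (normoxia). The labels describe 4 culture flasks, 2 hypoxic and 2 normoxic, hybridised as 2 pairs of a hypoxic and a normoxic flask on two-colour Agilent arrays. Each pair was hybridised in both dye orientations, which gave 4 arrays on 1 slide. The 2 arrays of a pair carry the same RNA, so the pair is the replicate and each gene's log2 ratio is the mean of n = 2 pairs, given with the SD between them. Values for an alternative or a further probe stand without an SD. The number of pairs limits the precision of every value. Between 52.6% and 61.8% of the 41000 probes were well above background in the hypoxic channel of an array, and between 56.6% and 61.4% in the normoxic channel. No spot was saturated.

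The comparison of hypoxia with normoxia addresses, per the series title, the response of liver cancer cells to prolonged low oxygen. Among named genes well above background on all 4 arrays in both conditions, the largest rises were those of EDN2, a vasoconstrictor peptide (log2 ratio 5.19 ± 0.49, SD), ANGPTL4, a secreted inhibitor of lipoprotein lipase (5.03 ± 0.20), and LOX, a collagen crosslinking enzyme (4.43 ± 0.33). They were followed by KRT37, a hair keratin (4.12 ± 0.0031), ADM, a vasodilator peptide (3.81 ± 0.12), IGFBP3, a carrier of insulin-like growth factors (3.66 ± 0.25), HILPDA, a lipid droplet protein (3.52 ± 0.68), OLFML2A (3.44 ± 0.26), LOXL2 (3.41 ± 0.59), PFKFB4 (3.29 ± 0.67), NPPB, the precursor of B-type natriuretic peptide (3.28 ± 0.25), and MB, the oxygen-binding protein myoglobin (3.21 ± 0.22). The largest falls among such genes were smaller: CITED4, a co-regulator that binds p300 and CBP (-2.50 ± 0.20), the zinc finger gene ZNF239 (-2.48 ± 0.90), NABP1 (-2.39 ± 1.08), RETREG1, a receptor for autophagy of the endoplasmic reticulum (-2.34 ± 1.12), CTH, which makes cysteine from cystathionine (-2.18 ± 0.65), and DKK1, a secreted Wnt inhibitor (-2.18 ± 0.45). MYPN (-2.17 ± 0.33), RRS1 (-2.15 ± 0.01), LCMT2 (-2.13 ± 1.30), BEX2 (-2.09 ± 1.16) and PPP1R10 (-2.07 ± 1.09) were also among the 12 largest falls. By the rule that chose them, these genes had the same sign on all 4 arrays. The ratio of 6 of these falls differed by over 2-fold between the pairs, at -1.84 in pair 2 for ZNF239, -1.63 for NABP1, -1.55 for RETREG1, -1.21 for LCMT2, -1.27 for BEX2 and -1.30 for PPP1R10. SLC7A11 stood lower, at -3.06 ± 0.99, but was well above background on only 2 of the 4 arrays in hypoxia.

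Of 12763 genes tested, 3328 passed an adjusted p of 0.05 in limma, of which 1475 rose and 1853 fell. A total of 676 genes changed at least 2-fold the same way in both pairs, 439 upward and 237 downward. That number depended on the processing of the signals. It was 394 with the marked local backgrounds kept, 546 without background correction, 1010 with the scanner software's processed signals and 1014 with the authors' table. The count of 3328 rests on a spread that limma took as common to all genes (infinite prior degrees of freedom). The smallest log2 ratio called was therefore 0.61 in size. The count was 0 without moderation of the spread, where p-values on 1 degree of freedom could hardly pass. It was 0 without the filter on dim probes and 6 when the pairing of flasks was ignored. Median centring in place of loess shifted the median of all genes from -0.05 to -0.16 and the share of calls that rose from 44.3% to 31.2%. Among the calls, 20 genes had pairs opposite in sign and 384 had pair ratios over 2-fold apart.

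**Figure D1:**
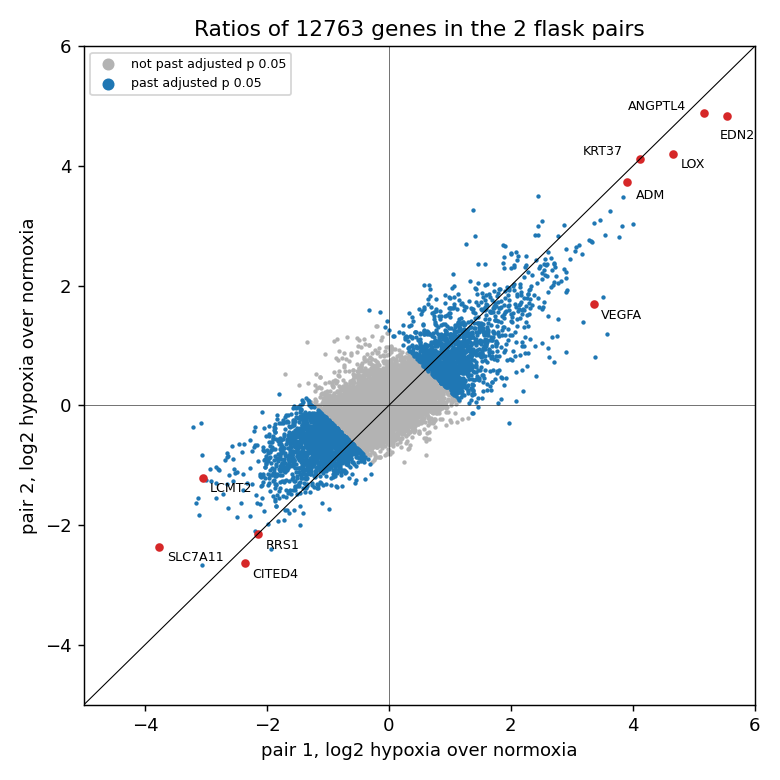
Each point is 1 of 12763 genes, with its log2 ratio of hypoxia over normoxia in pair 1 on the horizontal axis and in pair 2 on the vertical axis, the line marking equal values; blue points passed the threshold and red points are named. The ratios of the pairs correlated with r = 0.778 across genes, and points far below 0 lie further out in pair 1 than in pair 2.

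The pairs did not respond to the same extent. Across genes, which are not independent replicates, the ratios of the 2 pairs correlated with r = 0.778, against 0.950 and 0.911 between the dye orientations of pair 1 and of pair 2. In pair 1, 893 genes were at least 2-fold higher and 1245 at least 2-fold lower in hypoxia, while in pair 2 the numbers were 602 and 280. The ratio of 6765 genes depended on the dye orientation in a fit over the 4 arrays, with a median difference between orientations of 0.14 on the log2 scale. The spread in that fit is between arrays of the same RNA, and the orientation cancels in the mean of a pair. With the local backgrounds that the scanner software had marked kept in the correction, the number was 1.

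Of 44 gene lists tested, 20 passed, 15 of them shifted upward and 5 downward. None passed with an estimated correlation, a form that on 1 residual degree of freedom could hardly call any list. The 15 include the study's prognostic signature, which was chosen on these samples and has members in both directions. The lists share members, so their calls are not separate results. The camera p-values with the preset correlation compare a list's genes with the other genes and do not measure the variation between flasks. CA9, CA12, VEGFA, ANGPTL4, GBE1, PPP1R3C, KDM3A, P4HA1, EGLN3 and ERO1A are among the canonical hypoxia targets that are also in other lists below. EGLN3 is in the list of the HIF pathway and in the signature, and ERO1A in the signature and the unfolded protein response list. SLC16A3 is in both the glycolysis list and that of carbonic anhydrases and pH. Established targets of the hypoxia-inducible factors rose. Of 38 measured canonical hypoxia targets, 33 rose and none fell (34 past the threshold when adjusted over the list alone), with a median log2 ratio of 2.20. The list passed camera with an adjusted p of 3.01e-63; the adjusted p was 0.69 with an estimated correlation. NDRG1, a stress-response gene, rose by 2.55 ± 0.14, CA9, a cell-surface carbonic anhydrase, by 2.58 ± 0.42, VEGFA, an angiogenic growth factor, by 2.52 ± 1.18 (1.69 in pair 2), and BNIP3, a mitophagy receptor, by 2.30 ± 0.27. Of 13 measured genes of the HIF pathway itself, 4 rose and 1 fell (5 adjusted over the list alone; camera adjusted p = 0.000872, and 0.69 with an estimated correlation). The prolyl hydroxylases that mark HIF for degradation went in different directions, with EGLN3 at 3.20 ± 0.49 and EGLN1 at 2.03 ± 0.19 higher and EGLN2 at -0.67 ± 0.08 lower; EGLN2 did not pass with an intensity trend in the spread (adjusted p = 0.0511). ARNT2, a partner of HIF subunits, was higher at 2.80 ± 0.04. CREBBP rose on average (0.92 ± 1.23) but by only 0.05 in pair 2, and neither its mean over probes of 0.23 nor its ratio with median centring of 0.69 passed. HIF1A (0.22 ± 0.47) and EPAS1 (0.20 ± 0.24) did not pass, and HIF1A had the opposite sign (-0.03) on the arrays with hypoxia in Cy3. VHL stood at -0.45 ± 0.69 and passed in 3 alternatives, with an adjusted p of 0.0391 for the mean over its probes, 0.0136 with an intensity trend and 0.0259 with marked local backgrounds kept.

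Genes of glucose uptake and glycolysis rose together. Of 23 measured members, 19 rose and none fell (21 adjusted over the list alone), with a median of 1.30 and an adjusted p of 1.12e-22 by camera; the adjusted p was 0.69 with an estimated correlation. Examples are the neuronal enolase ENO2 (3.02 ± 0.36), MXI1, an antagonist of MYC (2.82 ± 0.33), the glucose transporters SLC2A3 (2.42 ± 0.70) and SLC2A1 (1.95 ± 0.03), and LDHA, which makes lactate from pyruvate (1.30 ± 0.12). In the list of gluconeogenesis and glycogen 8 of 14 rose and 1 fell (9 adjusted over the list alone; adjusted p = 6.31e-05 by camera, and 0.69 with an estimated correlation). These included glycogen phosphorylase PYGL (1.96 ± 0.03), the glycogen-targeting subunit PPP1R3C (1.83 ± 0.07) and the glycogen branching enzyme GBE1 (1.68 ± 0.37). PCK1, an enzyme of gluconeogenesis, stood at 2.66 ± 1.20 (1.81 in pair 2) on a probe well above background on 1 of 4 arrays in normoxia, and at 0.53 on its other probe. Of 9 measured carbonic anhydrases and pH regulators, 4 rose (4 adjusted over the list alone; adjusted p = 0.0113, and 0.69 with an estimated correlation), among them CA12 (1.41 ± 0.04), CA8 (0.76 ± 0.36) and the lactate exporter SLC16A3 (1.01 ± 0.18), while SLC16A1 stood at 0.47 ± 0.09. This list lost its call without the filter on dim probes (adjusted p = 0.186), as did the HIF pathway (0.111), which also lost it when the pairing of flasks was ignored (0.0679).

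Most measured genes of collagen and matrix modification rose. Of 14 members, 11 rose and none fell (12 adjusted over the list alone; adjusted p = 2.27e-15, and 0.69 with an estimated correlation), with the collagen prolyl hydroxylase P4HA1 at 2.38 ± 0.18 and the lysyl hydroxylase PLOD2 at 2.27 ± 0.22. Of 11 measured angiogenic and secreted factors, 6 rose and 3 fell (9 adjusted over the list alone; adjusted p = 5.79e-12, and 0.69 with an estimated correlation). The ribonuclease ANG was higher at 2.01 ± 0.02, and FGF21, a hepatic endocrine factor, was lower at -1.03 ± 0.02. Metallothioneins, which bind zinc and copper, rose in 10 of 11 cases (10 adjusted over the list alone; adjusted p = 1.02e-09, and 0.69 with an estimated correlation), with MT1M at 2.09 ± 0.63, MT1F at 1.86 ± 0.31, MT1E at 1.41 ± 0.06 and MT1X at 1.34 ± 0.07. Their sequences are near-identical, so their probes may share signal and are not separate measurements.

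Among inflammatory and early response genes more rose than fell. Of 14 measured NF-kB targets, 9 rose and none fell (9 adjusted over the list alone; adjusted p = 1.25e-05, and 0.69 with an estimated correlation), including the cytokine IL1B (1.97 ± 0.01), PTGS2, an inducible prostaglandin synthase (1.25 ± 0.15), and the chemokine CCL20, which was 2.83-fold higher (SD 0.17 on the log2 scale). TNFAIP3 was 2.82-fold higher, with log2 ratios of 2.15 in pair 1 and 0.84 in pair 2 (SD 0.92). Among 20 immediate early genes 9 rose and 1 fell (11 adjusted over the list alone; adjusted p = 0.000327, and 0.69 with an estimated correlation), with IER3 at 2.97 ± 0.75, the transcription factors JUN at 2.40 ± 0.20 and JUNB at 1.48 ± 0.10, and ZFP36 at 1.66 ± 0.13. The median of this list was 0.17 in pair 1 and 0.61 in pair 2. Of 15 replication-dependent histones, 6 rose and 1 fell (7 adjusted over the list alone; adjusted p = 0.00881, and 0.75 with an estimated correlation), with H1-4 at 1.51 ± 0.48, H2AC18 at 1.51 ± 0.24 and H1-3 at 1.49 ± 0.46, while H4C3 stood at -0.20 ± 0.44; the median was 0.71 in pair 1 and 0.16 in pair 2. Histone genes are similar in sequence too, and the list stood at an adjusted p of 0.0538 without the filter on dim probes. Of 9 measured histone and DNA demethylases, which use oxygen as a substrate, 4 rose and 1 fell (6 adjusted over the list alone; adjusted p = 0.0274, and 0.69 with an estimated correlation). KDM3A (1.73 ± 0.24), KDM5B (1.08 ± 0.34) and KDM2B (0.77 ± 0.04) were higher and KDM4A (-0.72 ± 0.02) was lower, and the list's median was 0.73 in pair 1 and 0.31 in pair 2. KDM2B did not pass with median centring (0.54), and the list's adjusted p was 0.0578 with the scanner software's processed signals and 0.0524 on the arrays with hypoxia in Cy5.

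Most measured genes of ribosome biogenesis fell. Of 24 members, 17 fell and 1 rose (18 adjusted over the list alone), with medians of -0.88 in pair 1 and -0.89 in pair 2 and an adjusted p of 5.9e-08; the adjusted p was 0.69 with an estimated correlation. RRS1, an assembly factor of the large subunit, fell by 2.15 ± 0.01 on the log2 scale, the nucleolar proteins NOP58 and NOP56 stood at -1.89 ± 1.03 (-1.16 in pair 2) and -1.52 ± 0.47, and RCL1 at -1.56 ± 0.13. None of 26 cytosolic ribosomal proteins passed the test or did so adjusted over the list alone (adjusted p = 0.60, and 0.75 with an estimated correlation). Their median of 0.02 was -0.03 with the processed signals, and with median centring the list passed with a shift upward relative to the other genes (adjusted p = 1.79e-05). RPS27 stood at 0.11 ± 0.08. Of 27 genes of the mitochondrial ribosome and protein import, 12 fell and 1 rose (15 adjusted over the list alone; adjusted p = 0.00309, and 0.69 with an estimated correlation), with MRPL15 at -1.49 ± 0.33, the mitochondrial transcription factors TFB2M at -1.11 ± 0.35 and TFAM at -1.01 ± 0.50, and TIMM10 at -1.02 ± 0.02.

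Among genes of the amino acid response, many of them targets of the transcription factor ATF4, more fell than rose. Of 23 measured, 13 fell and 2 rose (15 adjusted over the list alone; adjusted p = 1.61e-05, and 0.69 with an estimated correlation). The cystine transporter SLC7A11 stood at -3.06 ± 0.99 (above background on 2 of 4 hypoxic arrays, and -2.36 in pair 2), CHAC1, which degrades glutathione, at -2.03 ± 0.56, DDIT3, a stress transcription factor, at -1.91 ± 0.21, and asparagine synthetase ASNS at -1.55 ± 1.28 (-0.64 in pair 2), or -0.27 on its dimmer probe. The list's median was -1.24 in pair 1 and -0.53 in pair 2. Of 25 genes of cholesterol synthesis and uptake, 10 fell and 1 rose (13 adjusted over the list alone; adjusted p = 0.00214, and 0.69 with an estimated correlation). IDI1 (-1.36 ± 0.45) and LSS (-1.22 ± 0.13) were lower, and INSIG1, which holds back sterol synthesis, was higher at 1.28 ± 0.12. Of 24 DNA repair genes, 8 fell and none rose (8 adjusted over the list alone; adjusted p = 0.00749, and 0.75 with an estimated correlation), among them BRCA1 (-1.16 ± 1.15), POLE2 (-1.14 ± 1.05) and EXO1 (-0.94 ± 0.50). For BRCA1 and POLE2 the ratio in pair 2 was -0.34 and -0.40, and the median of the DNA repair list was -0.61 in pair 1 and -0.18 in pair 2.

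**Figure D2:**
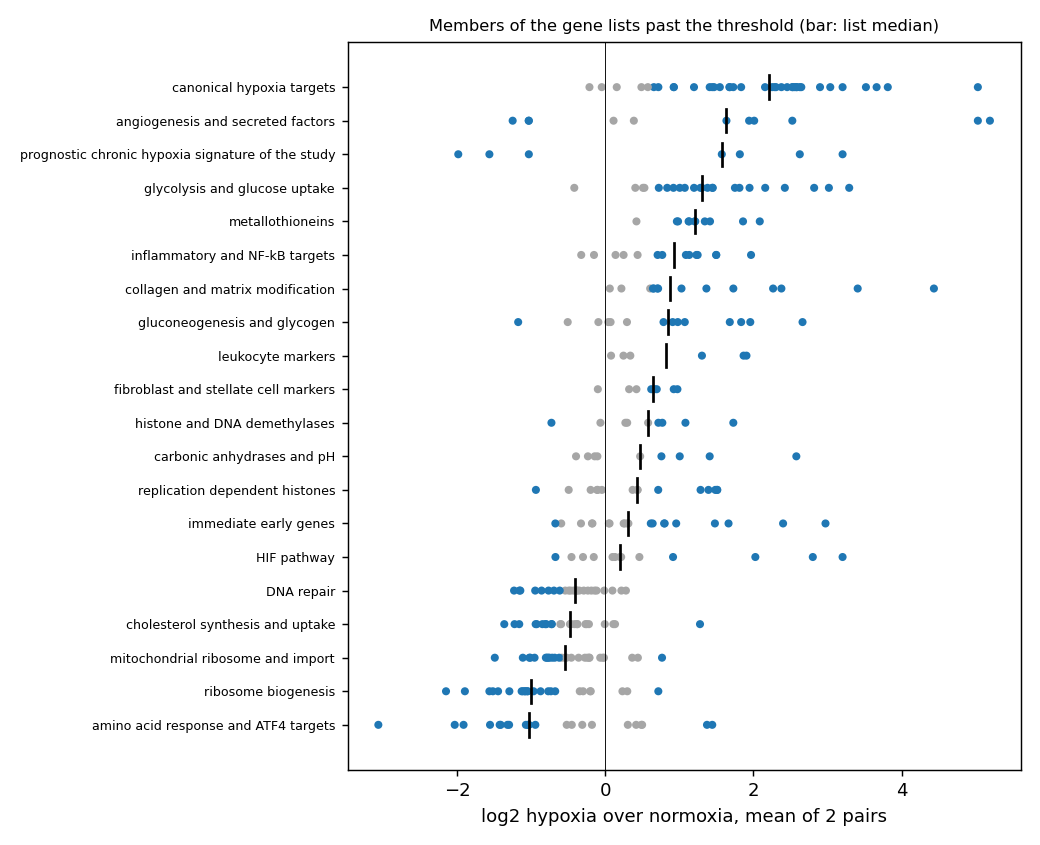
Each point is a measured member of 1 of the 20 gene lists past the threshold, at its log2 ratio of hypoxia over normoxia (horizontal axis, mean of 2 pairs); blue members passed the test, grey members did not, and the bar is the list median. Canonical hypoxia targets had a median of 2.20 and the amino acid response list one of -1.03.

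The 7 genes known from the study's prognostic signature all passed the test. CCNG2 (1.82 ± 0.30), EGLN3 (3.20 ± 0.49), the oxidoreductase ERO1A (2.63 ± 0.31) and WDR45B (1.57 ± 0.15) were higher, and FGF21 (-1.03 ± 0.02), MAT1A, which makes S-adenosylmethionine in liver (-1.98 ± 0.01), and RCL1 (-1.56 ± 0.13) were lower. The study chose this list on these samples, so neither the count nor its 7 calls adjusted over the list alone are independent evidence. The list's adjusted p was 0.0119 by camera, with members in both directions, and 0.69 with an estimated correlation. The call was also lost with the processed signals (0.129), the authors' table (0.157), median centring (0.0864), no filter on dim probes (0.457), the pairing ignored (0.275) and without the 2 arrays on which the background correction first failed (0.222).

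Single genes of liver functions changed. At gene level the lists named next did not pass, except in the alternatives given. With every probe tested on its own 26 lists passed camera, 20 of them shared with the main test, and the further lists are not named here. Of 19 hepatocyte plasma proteins 5 fell and none rose (adjusted p = 0.0854), with APOB at -1.51 ± 0.15, APOH at -1.36 ± 0.20, albumin ALB at -0.79 ± 0.39 and TTR at -0.77 ± 0.15, while TF stood at -0.21 ± 0.07. ALB no longer passed with median centring (-0.49), nor TTR on the arrays with hypoxia in Cy5 (-0.57), and the list passed without the filter on dim probes (adjusted p = 0.0104) and with marked local backgrounds kept (0.0259). Of 24 genes of the urea cycle and amino acid catabolism 3 rose and 6 fell (0.0671), with HGD at -1.02 ± 0.03; this list passed with an intensity trend in the spread (adjusted p = 0.0366) and on the arrays with hypoxia in Cy5 alone (0.0335). In drug metabolism and bile acids 1 rose and 5 fell of 13 (0.413), among them SULT2A1 (-1.21 ± 0.09), CYP3A7 (-1.13 ± 0.15), CYP1A1 (-1.01 ± 0.25) and CYP3A4 (-0.91 ± 0.03). Of 12 hepatocyte transcription factors 3 rose and 2 fell (0.989), with the bile acid receptor NR1H4 at -1.23 ± 0.25 and NR0B2 at -1.11 ± 0.10. The probe of NR1H4 was well above background on only 1 of 4 arrays in hypoxia, so its ratio rests on signal near background. CEBPA stood at 1.26 ± 0.44 on its brightest probe, but its probes disagreed and their mean was -0.72. Coagulation and complement had 2 rises and 2 falls among 23 genes (1), with C1R at 1.47 ± 0.12 and F12 at 1.25 ± 0.10. The acute phase response had 5 rises and 2 falls among 14 (0.166), with SAA1 at 1.46 ± 0.43 and SAA4 at -1.58 ± 0.28. Fetal and hepatoblast markers had 2 rises and 3 falls among 11 (0.479), with H19 at 1.76 ± 0.04 and AFP at -0.83 ± 0.09.

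Of the other lists of mitochondrial, lipid and redox metabolism, those named next did not pass at gene level. The tricarboxylic acid cycle had no rise and 5 falls among 22 genes (adjusted p = 0.239), including IDH1 (-1.17 ± 0.73) and IDH3A (-0.82 ± 0.07). Oxidative phosphorylation had 1 rise and 2 falls among 31 (0.649), the rise being that of COXFA4L2, older name NDUFA4L2 (2.41 ± 0.52). Fatty acid oxidation had 2 rises and 4 falls among 19 (0.479), with the coactivator PPARGC1A at -1.33 ± 0.17. Lipid storage and fatty acid synthesis had 2 rises and 5 falls among 21 (0.618), with GPAM at -1.48 ± 0.80 and MLXIPL, whose probes disagreed, at -1.43 ± 0.11. Iron and heme had 3 rises and 1 fall among 21 (0.517), with the transferrin receptor TFR2 at 1.40 ± 0.30. Antioxidant and NRF2 targets had 2 rises and 3 falls among 24 (0.493), with ABCC3 at 1.42 ± 0.26 and TXNRD1 at -1.05 ± 0.29.

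Of 42 cell cycle and proliferation genes 2 rose and 4 fell (adjusted p = 0.913), with BUB1 at 1.20 ± 0.19 and MCM3 at -0.77 ± 0.22, which did not pass with median centring (-0.53). Kinase inhibitors and p53 targets had 6 rises and 4 falls among 23 (0.517), with GADD45B at 1.46 ± 0.21 and SESN2 at -1.04 ± 0.28. The unfolded protein response had 3 rises and 3 falls among 22 (0.245), with ERO1B at 1.00 ± 0.17 and XBP1 at -1.30 ± 0.43; with median centring this list passed (0.0412). Heat shock and protein folding had 4 rises and 3 falls among 15 (0.413), with HSPA6 at 2.32 ± 1.34 (1.38 in pair 1). Autophagy and mitophagy had 4 rises and 2 falls among 20 (0.175), with BNIP3L at 2.28 ± 0.53 and SQSTM1 at -1.33 ± 0.02. Apoptosis regulators had 2 rises and 2 falls among 19 (0.60), with CASP9 at -1.36 ± 0.53. The epithelial-mesenchymal transition list had 5 rises and 2 falls among 16 (0.413), with the integrin ITGA5 at 2.52 ± 0.55, SNAI1 at 1.74 ± 0.14 and CLDN1 at -1.43 ± 0.77. Wnt targets had 2 rises and 1 fall among 14 (0.517), with NKD2 at 2.36 ± 0.48, and the interferon response had 2 rises and 2 falls among 19 (0.618), with IRF7 at 2.09 ± 0.09 and IFIT2 at -1.82 ± 0.99 (-1.12 in pair 2).

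Markers of other cell types were measured in the same flasks. Of 14 leukocyte markers 6 were measured, of which 3 rose and none fell, among them CD68 (1.87 ± 0.37) and CSF1R (1.31 ± 0.40) (3 adjusted over the list alone; adjusted p = 0.000717, and 0.69 with an estimated correlation). Of 8 measured fibroblast and stellate cell markers 5 rose, among them ACTA2 (0.97 ± 0.46), DCN (0.92 ± 0.42), PDGFRB (0.70 ± 0.15) and TAGLN (0.66 ± 0.60), with an adjusted p of 0.0231 for the list, 0.75 with an estimated correlation and 0.058 with the processed signals. With median centring PDGFRB (0.49) and TAGLN (0.45) did not pass, nor did PDGFRB on the arrays with hypoxia in Cy3 (adjusted p = 0.0969). TAGLN was 1.09 in pair 1 and 0.24 in pair 2, and it also lost its call with the processed signals (adjusted p = 0.0593), the authors' table (0.0641), an intensity trend (0.0559), hypoxia in Cy5 alone (0.0638) and without the arrays on which the background correction first failed (0.0533). The list medians were 0.83 and 0.31 in pairs 1 and 2 for the fibroblast markers and 1.12 and 0.60 for the leukocyte markers. For comparison, the medians in pairs 1 and 2 were 1.06 and 0.91 for the matrix list and 0.72 and 0.84 for the NF-kB targets. Whether the markers moved with those genes was not tested. Cholangiocyte markers had 3 rises and 1 fall among 9 (0.144), with TFF3 at 2.06 ± 0.78 and KRT7 at -1.26 ± 0.13. Of 12 endothelial markers 2 were measured, too few for a list test, and ESAM stood at 0.69 ± 0.14; it did not pass with median centring (0.51), as the mean over its probes (0.54) or on the arrays with hypoxia in Cy3 (0.59).

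For 66 genes the probe was well above background on all 4 arrays in 1 condition and on none in the other, which gives only a bound. Of these, 55 had a gene symbol, a bound over 1-fold and no other probe above background in the dim condition. Bounds compare the bright condition's mean with that of the dim condition, per channel after loess and Aquantile. Dim levels under the lowest signal well above background were first raised to it. A dim level over it kept its measured value. COL13A1, a transmembrane collagen, was at least 3.57-fold higher in hypoxia (adjusted p = 1.21e-15 in limma), TCP11L2 at least 3.01-fold (3.68e-09), PTGS1 at least 2.97-fold (2.29e-12) and DUOX2 at least 2.55-fold (4.32e-09). These bounds are for the mean of the pairs: the measured log2 ratio of a single pair lay below the bound for COL13A1 (1.41 in pair 1), TCP11L2 (0.98 in pair 2) and DUOX2 (1.18 in pair 2). KLHL4 was at least 2.46-fold lower in hypoxia (7.56e-07) and the protocadherin PCDH10 at least 2.41-fold lower (2.12e-10). Other genes named above were well above background on only some arrays of a condition: in hypoxia SULT2A1 on 2 and CYP3A4, FGF21 and IFIT2 on 3 of 4, and in normoxia MT1M on 2 of 4. Besides the genes whose probes are described above, a further probe gave a smaller ratio in size for CITED4 (-1.33), NABP1 (-1.53), RETREG1 (-1.69), VEGFA (1.41), ERO1A (2.17), SLC2A3 (2.06), TFF3 (1.49), H19 (1.37), TNFAIP3 (1.17), XBP1 (-0.92), CCNG2 (0.69), NKD2 (0.66), PTGS2 (0.56), KDM5B (0.46), CLDN1 (-0.36), SLC16A3 (0.11) and LSS (-0.10).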

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

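Probes without a gene name lie outside the comparison of named genes. Of 4775 such probes tested in the same way, 1053 passed the threshold, 504 higher and 549 lower in hypoxia, and 185 changed at least 2-fold the same way in both pairs. Their genes were not analysed here.

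The tests of the next pattern were chosen after it was seen. At least 2-fold lower in hypoxia were 1245 genes in pair 1 and 280 in pair 2. A common compression of the ratios of pair 2 would shrink the canonical hypoxia targets as well, but their median in pair 1 was 0.942 times that in pair 2 (bootstrap interval 0.845 to 1.18), against a ratio of 1.39 for the SD of all genes. Another background correction or normalization left at least 3.16 times as many such genes in pair 1, and the smaller ratio of the dye orientations was 3.93, so neither accounts for the whole. In levels per flask, the 1245 genes were lower in the hypoxic flask of pair 1 than in that of pair 2 by a median of 0.88 and differed by -0.11 between the normoxic flasks; these genes were picked for their fall in pair 1. No biological explanation was tested, since the labels describe no difference between the pairs.

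The test of leukocyte markers was also chosen after their rise was seen. Leukocyte RNA in the hypoxic flasks could raise CD68 and CSF1R. CD68 and CSF1R themselves were well above background on all 4 arrays in normoxia as well as in hypoxia. Of 5 transcripts abundant in cells that carry CD68 and CSF1R, 2, PTPRC and AIF1, were not well above background in either channel of any array. TYROBP was well above background on 2 of 4 arrays in hypoxia and on 2 in normoxia, and ITGAM on 2 and 1. LYZ stood at 0.34 without passing. The level that the needed share of such cells would give was not measured, so this explanation stays open. Probes that bind other transcripts were not tested.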

How the results depend on the processing

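The alternatives that keep the marked backgrounds in the correction, drop the arrays on which it failed, or drop moderation were chosen after seeing the data. The count of genes past the threshold moved most in 3 alternatives. The one without moderation kept the genes and the pairs, but changed the spread and took its p-values from 1 degree of freedom. There an adjusted p under 0.05 over 12763 genes was hardly within reach (smallest 0.478). Its count of 0 therefore says little about the genes. The others changed the genes tested or the pairing as well, and for them the cause was not tested. Without moderation of the spread 0 genes passed, 0 rose and 0 fell in limma, with 1291 at an unadjusted p under 0.05, against 4587 with moderation. Without the filter on dim probes, where the prior had 2.49 degrees of freedom, 0 passed, 0 rose and 0 fell, with 5073 at an unadjusted p under 0.05. With no replicate block, so that the pairing was ignored, 6 genes passed, 6 rising and 0 falling, with 2732 at an unadjusted p under 0.05. In the other alternatives with a test, 2948 to 4105 genes passed, apart from testing every probe, which with more units tested gave 5582 calls, 2547 up and 3035 down, and 1034 probes changed 2-fold in both pairs. Median centring gave 970 rises, 941 of them shared, and 31.2% of calls upward against 44.3%; the dye orientation then affected 11887 genes. The cause was not tested. With marked backgrounds kept, 394 genes changed 2-fold in both pairs and 1 gene depended on dye orientation. Without the arrays on which the correction failed, 2948 genes passed, 2920 of them shared, and 682 changed 2-fold in both pairs. With either pair left out there is no test, and 882 to 2138 genes changed 2-fold in the remaining pair. Lists past the threshold numbered 17 to 26, and none of the 20 lists turned the sign of its median in the alternatives at gene level. CEBPA reversed to -0.72 with the mean over its probes, which disagree. The planned fit of 4 arrays with the pair as a random block was not run, since duplicateCorrelation gave no estimate for 4 arrays and 2 terms. Signal over background limits dim genes to bounds.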

Other observations

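Aminoacyl-tRNA synthetases, which charge tRNAs for translation, were not described above. Of 12 cytosolic synthetases known as ATF4 targets, 9 fell and none rose, with TARS1 at -1.27 ± 0.93 (-0.61 in pair 2), MARS1 at -1.12 ± 0.78 and GARS1 at -0.97 ± 0.60, while of 8 others 2 fell, FARSB (-0.85 ± 0.49) and RARS1 (-0.78 ± 0.61). The genes named from these sets were chosen after their values were seen. SR splicing factors were also lower: without SRSF3, 8 of 11 fell and 1 rose, with SRSF6 at -1.81 ± 0.38, TRA2B at -1.03 ± 0.21 and SRSF10 at -1.02 ± 0.61 lower and SRSF4 at 0.97 ± 0.67 higher.

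The test on the unfolded protein response was chosen after its result was seen; the tests on synthetases and SR factors were set before their values were looked at, on lists drawn up after the main results. One hypothesis for the fall of the amino acid response list is lower ATF4 activity, which may also lower the synthetases that ATF4 induces. Their median was 0.78 lower than that of the other synthetases (difference -0.781), in the direction of the hypothesis. The two-sided permutation p was 0.00031 over genes, which are not independent replicates. The set passed camera (p = 1.31e-05) but not with an estimated correlation (p = 0.411), which on 1 residual degree of freedom could hardly pass. A lower unfolded protein response as a whole stays open: that list's median of 0.187 (bootstrap interval -0.0006 to 0.388) lies over 3 rises and 3 falls and decides nothing. ATF4 protein and translation were not measured, and the falls were larger in pair 1.

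A second hypothesis, raised by SRSF3 and PPP1R10, is that SR splicing factors may fall as a group. The family without SRSF3 shifted downward in camera (p = 0.00418), though not with an estimated correlation (p = 0.296), and SRSF4 went the other way. Whether splicing differed was not tested.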
